A study of Mus musculus with 14 samples.

How the data were processed

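RNA was measured in 14 samples of cortical astrocytes cultured from newborn mice: 6 wild-type samples, 4 samples lacking connexin43 (Cx43, encoded by Gja1) and 4 wild-type samples treated with a small interfering RNA (siRNA) against Cx43. Per the labels' protocols, 20 ug of total RNA per sample was labelled with Cy3 or Cy5, and the dyes are balanced within every group (3 and 3 wild-type, 2 and 2 null, 2 and 2 siRNA samples). Per the design text, the arrays carried spotted oligonucleotides of a mouse library, and 4 independent cultures were compared per group, while the labels list 6 wild-type samples. Nothing ties a sample to a culture, so the p-values measure only the spread between these samples, which may be technical. The siRNA was applied for 36 h per the design text and for 48 h per the protein protocol.

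The deposited table holds 1 log2 value per probe and sample, as the authors processed it; the scanner, background correction, filter and normalization steps are not given in the sources used here. The values show that each column was centred: within each of 48 print blocks of 700 probes (25 grid rows by 28 grid columns) the median of every sample was 0. Each column's median over all probes was 0. Missing values carry no reason, and whether they mark dim or damaged spots is unknown. No intensity, background or detection value was used here, so the signal over background behind each value is unknown, and the number of arrays limits the precision. Of 33600 probes, 18179 have 1 gene symbol, 87 have several and 15334 are unnamed here; the named probes cover 13661 genes. Gene identifiers were checked against a table of RefSeq genes of the GRCm38.p6 assembly, which changed 0 probe symbols. The same table gave the order of genes around Gja1 and the current symbols of the genes in the gene lists. From 1373 list entries, 1323 list genes were found in it, and entries not found were left out.

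Samples were grouped by their titles. The 3 contrasts (null against wild type, siRNA against wild type, null against siRNA) came from 1 linear model over all 14 samples as deposited, with dye as a covariate, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. Probes measured in at least 3 wild-type, 2 null and 2 siRNA samples were tested, 21584 in all. P-values were two-sided and adjusted by Benjamini-Hochberg per contrast, and a probe was called at an adjusted p under 0.05. Gja1 was also tested by an exact two-sided permutation of its group means. The groups, the model, the 37 gene lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined.

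Gene lists were tested with limma's camera on the moderated statistics (cameraPR) with a preset correlation of 0.01, each gene represented by its brightest probe. Camera with an estimated correlation and fry were run beside it on probes measured in every sample. Both treated the samples as independent. Of the list genes, 1017 had a tested probe in the fit of the table as deposited. The lists with results given in the text cover interferon response, NF-kB inflammation, reactive astrocytes, astrocytes, microglia, oligodendrocytes, fibroblasts and mural cells, ependyma and choroid plexus, connexins and pannexins, purinergic signalling, the Nrf2 oxidative stress response, the proteasome, ribosomal proteins, translation factors, heat shock and unfolded protein response, the G2/M cell cycle, immediate early genes, and p53 together with cell cycle arrest. The last is shortened to p53 below. Of 36 reactive astrocyte genes, 9 stand in another list, as do 4 of 46 interferon genes, 3 of 38 inflammation genes and 3 of 32 microglia genes. No literature or count of cells was used, so how many list genes astrocytes themselves express is unknown.

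Named genes were Gja1, the up to 8 largest rises and falls per contrast against wild type and the 5 largest each between null and siRNA among called probes with 1 symbol whose samples all lay on the same side of the reference mean of the same dye. Where too few passed, the smallest unadjusted p filled up. Up to 3 called members of lists that passed or held a called member were added, with 12 genes named in advance whatever their values; clone names were left out. Of those 12, Gjb2, Gjb6 and Gfap were measured in too few samples to be tested.

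The columns of wild-type replicates 1, 2 and 5 did not follow the other samples, which led to further fits chosen after seeing the data. In the first 2 of these columns, runs of values matched the other samples 1 grid row away. Each of 1344 block columns was placed, for both samples together, at the grid row where its values correlated best with the mean of the 11 other samples: 1253 were placed at r of at least 0.5, 827 of them by moving 1 row up and 381 without a move, and 91 were left out. The median r was 0.935 at the chosen place and 0.232 at the next best. Because the place was chosen to match the other samples, it favours likeness between these columns and the rest.

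Among replicates 1 to 4 of all groups, replicates 1 and 2 deviated from their group means opposite to replicates 3 and 4, with correlations between -0.618 and -0.139 in the realigned table, so these numbers were treated as 2 batches. Wild-type replicate 6 was placed with replicates 3 and 4, which the values support only in part: its deviations correlated at -0.136 to -0.043 with replicates 1 and 2 and at -0.092 to 0.207 with replicates 3 and 4 of the other groups. Without it the realigned fit called 9 probes for null, 887 for siRNA and 777 between them. Within each group, consecutive samples of opposite dye (1 and 2, 3 and 4) correlated at 0.927 to 0.991, more closely than other samples of the group, except wild-type replicates 5 and 6 at -0.041, and may share an array, which no label states. The second fit therefore used the 13 realigned samples without wild-type replicate 5, with dye and batch as covariates (20330 probes tested). The third fit added the pairs of consecutive samples as a random block (duplicateCorrelation, consensus correlation 0.539). The check of replicate pairing gave correlations between same-numbered samples of different groups of 0.273 to 0.653 over 12336 realigned probes, and of 0.256 to 0.653 over 1704 probes as deposited, and each pair exceeded 0.1, so the numbers were treated as pairs. Samples of another number in the same batch correlated at 0.412 to 0.612 (null and siRNA), 0.117 to 0.461 (null and wild type) and 0.129 to 0.375 (siRNA and wild type) after realignment, so number and batch are not separated by this check. The replicate block over replicates 1 to 4 is given beside the counts it changes.

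The code was tested on simulated data with 100 changed probes at each of 4 sizes, siRNA against wild type. At changes of 2, 3 and 6 on the log2 scale the fit of the 14 samples as deposited recovered 5, 30 and 87 of 100, with 8 false calls over 21584 probes. Those samples were simulated as independent and without misplaced values, while consecutive samples as deposited had a consensus correlation of 0.803. False calls under such a correlation were not simulated for the fit as deposited, so the 8 do not describe it in these data. The realigned fit with a batch term recovered 66 and 96 of 100 at 2 and 3, with 15 false calls over 20330 probes. When samples of a pair were simulated with a correlation of 0.5, that fit made 238 false calls for siRNA and 45 for null; with the pairs as a random block it made 21 and 0 and recovered 35 and 88 of 100. Counts of called probes and list members from the realigned fit are therefore given beside those from the fit with array pairs, except where single replicates were left out, for the replicate block and for splits of the samples. A simulated shift of the interferon list by 1 was called and 0 of the other lists were.

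Alternatives covered normalization, the dye term, single dyes, replicate blocks, array pairs, the samples and probes used, variance moderation, array weights, thresholds and leaving out each replicate. The realigned, batch and within-batch fits, the fits without wild-type replicates 1, 2 and 5, the permutation of Gja1 within batches and the simulations with correlated array pairs were added after seeing the data. For the comparison of null and siRNA changes, unchanged groups were simulated 20 times against the same controls. Other splits of the samples were counted, up to 100 per result. An offset before log2 was not run, because the deposited values already are log2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.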

Results

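Astrocytes are the glial cells that clear transmitters and couple to one another through gap junctions, channels built largely of Cx43 in these cells. The series compares the RNA of cortical astrocytes cultured from newborn wild-type mice (6 samples), from mice without a functional Cx43 gene (4 samples, called null) and from wild-type cultures treated with an siRNA against Cx43 (4 samples). Its title asks how the transcriptomes of null and knockdown astrocytes compare. Per the design text, Cx43 protein was reduced by at least 70% after siRNA treatment and the mRNA by 3.24 times. Between 17849 and 26826 of 33600 probes had a value per sample (53.1% to 79.8%).

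Of the 14 columns, 3 wild-type columns stood apart from the rest. Wild-type replicates 1 and 2 correlated with the mean of the other samples at r = 0.37 and r = 0.38 across probes, against 0.87 to 0.94 for 11 samples, although they correlated with each other at 0.975. After their values were moved to the grid row they matched, these correlations were 0.852 and 0.87. Wild-type replicate 5 correlated with the rest at r = -0.081, and its values ran from -2.08 to 0.87 with an SD of 0.48, while the other 13 samples had SDs of 2.32 to 2.81. The quantity in that column is unknown. Genes are not independent replicates, so these correlations describe columns only.

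**Figure D1:**
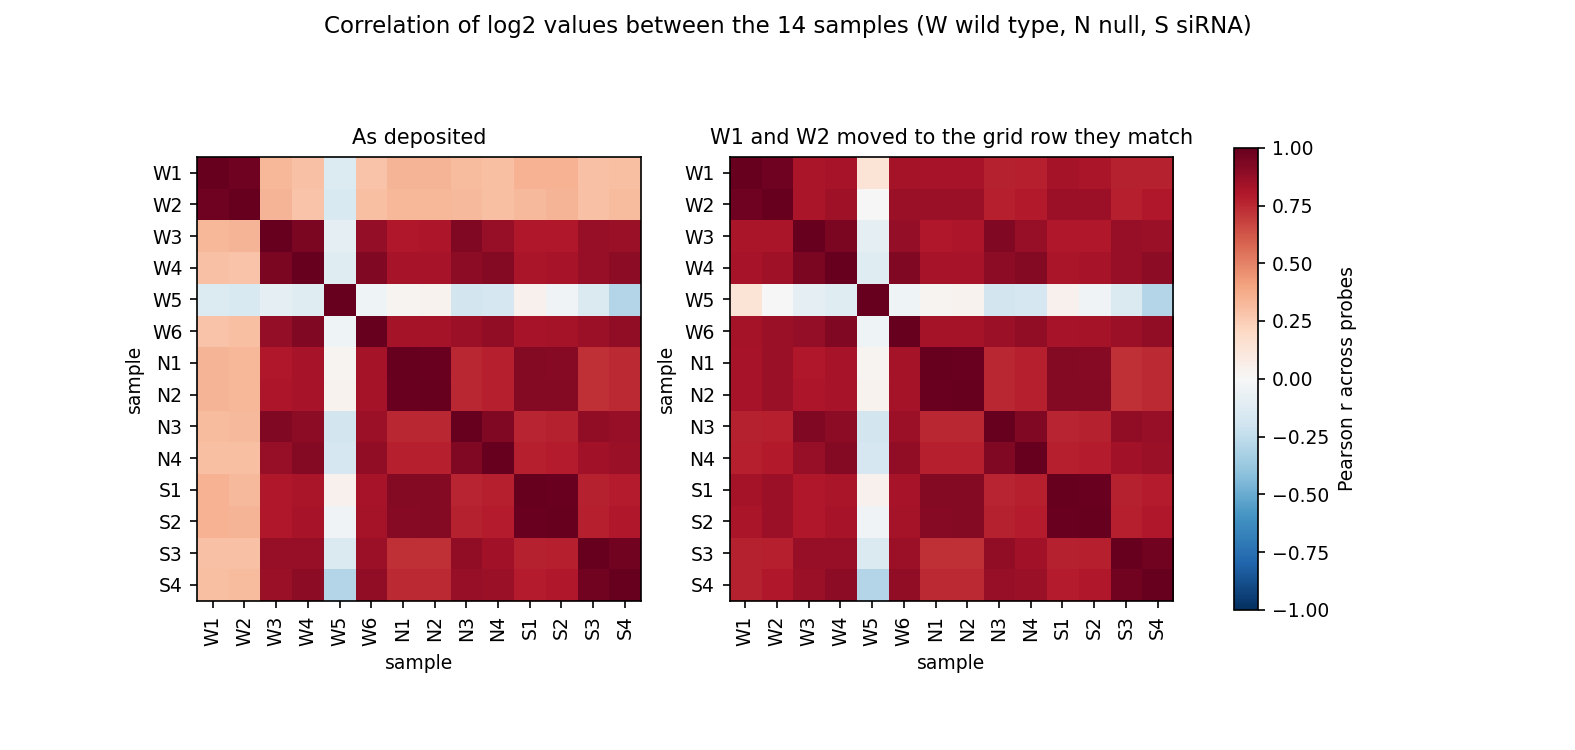
Pearson correlation across probes between each pair of the 14 samples, as deposited (left) and with wild-type replicates 1 and 2 (W1, W2) moved to the grid row they match (right); W is wild type, N null and S siRNA. W1 and W2 correlate with each other at 0.975 but with the mean of the other samples at 0.37 and 0.38 as deposited and 0.852 and 0.87 after the move, while W5 stays at -0.081.

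Gja1, the target of both manipulations, was lowest in the null samples. Its log2 value was 6.14 ± 1.35 (SD, n = 3) in the wild-type samples that measured it, 0.91 ± 2.33 (SD, n = 4) in the null samples and 3.81 ± 2.05 (SD, n = 4) in the siRNA samples. The null mean lay 37.7-fold below wild type (exact permutation p = 0.0286, the smallest the 35 splits allow), with all 4 null samples below all 3 wild-type samples. The siRNA mean lay 5.05-fold below wild type, a difference within the spread of the samples (exact permutation p = 0.229), and the null mean lay 7.46-fold below siRNA (exact permutation p = 0.171, where 70 splits allow 0.0286).

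Much of the spread in Gja1 followed the batches. Replicates 1 and 2 read -1.17 and -1.06 in null and 1.93 and 2.14 in siRNA samples; replicates 3 and 4 read 2.82 and 3.03 in null and 5.47 and 5.70 in siRNA samples. The wild-type values, 6.08, 7.53 and 4.82, came from replicates 3, 4 and 6 alone. The fold changes and permutations against wild type above therefore mix batch with group. So do the limma changes against wild type as deposited, which were fitted without a batch term. Within replicates 3 and above, Gja1 was lower than wild type by a log2 difference of -3.22 in null and of -0.56 (1.48-fold) in siRNA samples, and null minus siRNA was -2.66; within replicates 1 and 2 it was -3.14. Null lay below siRNA in all 4 same-numbered pairs, by log2 differences of -3.19 to -2.64 (exact permutation within the batches, p = 0.0556, the smallest the 36 splits allow). This permutation and those of the group means above treated all samples as independent. Consecutive null or siRNA samples (1 and 2, 3 and 4) read nearly alike and may share an array, so these p-values may be too small. In limma the null change was -5.21 ± 1.47 (SE, adjusted p = 0.578) as deposited, and -3.31 ± 0.54 (adjusted p = 0.0476) in the realigned fit with a batch term, where array pairs as a random block gave -3.07 with adjusted p = 0.394. Without null replicate 1, 2, 3 or 4, wild-type replicate 1 or 2, or siRNA replicate 1, 3 or 4 it did not pass either (changes of -3.42 to -3.27, adjusted p 0.0538 to 0.18), and without wild-type replicate 3, 4 or 6 too few values were left. The siRNA change there was -0.41 ± 0.54 (adjusted p = 0.72). Null minus siRNA was -2.90 ± 1.35 (adjusted p = 0.797) as deposited, passed at -2.90 ± 0.54 (adjusted p = 0.0152) in the realigned fit and did not with array pairs (0.154). The realigned fit without null replicate 2 or 4 or siRNA replicate 3 or 4 did not pass it either (adjusted p 0.052 to 0.0592). The position of the probe relative to the deleted part of the gene is not given in the sources used here.

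**Figure D2:**
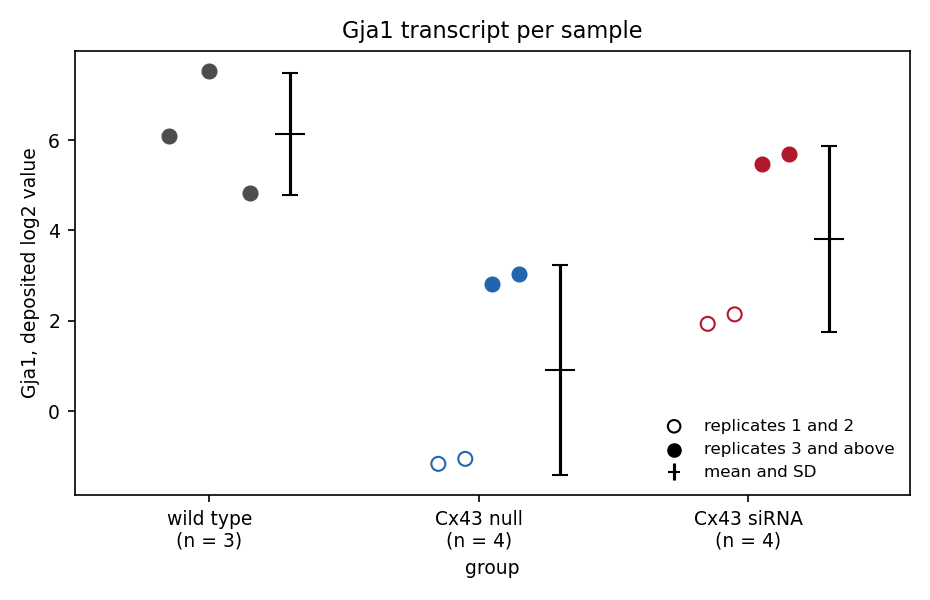
Deposited log2 value of Gja1 in each sample that measured it (open circles, replicates 1 and 2; filled circles, replicates 3 and above), with the mean and SD of each group (wild type n = 3, null n = 4, siRNA n = 4). The 4 null samples lie between -1.17 and 3.03, below the 3 wild-type samples at 4.82 to 7.53, and the siRNA samples lie between 1.93 and 5.70. No wild-type value came from replicates 1 and 2.

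Of 39 measured interferon response genes 9 rose in the siRNA samples as deposited, 38 had positive changes, and the median log2 change was 2.53. With array pairs as a random block 0 probes were called in the same 14 samples. An estimated correlation could be had only after realignment (adjusted p = 0.187 with an estimated correlation). Irf7, the transcription factor that amplifies type I interferon, rose by 5.97 ± 0.81 (SE, log2; 62.7-fold), the GTPases Tgtp1 and Ifi47 by 5.90 ± 0.66 and 5.66 ± 0.82, and Ifit1, which binds viral RNA, by 5.43 ± 0.93. Zbp1, a sensor of foreign nucleic acid, rose by 5.28 ± 0.77, the oligoadenylate synthetase-like gene Oasl1 by 4.68 ± 0.52, and the chemokine Cxcl10, the gene with the smallest adjusted p beside Hpgd, by 5.04 ± 0.46 (32.8-fold, limma adjusted p = 0.00113). The adjusted p of the others ran from 0.00333 (Tgtp1) to 0.0421 (Ifit1).

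Of 31 reactive astrocyte genes 6 rose and none fell (median 1.06), and of 27 NF-kB inflammation genes 3 rose (median 1.48). As deposited both lists had too few complete probes for an estimated correlation; after realignment the adjusted p = 0.634 and 0.181 with an estimated correlation. Steap4, a metalloreductase induced by inflammation, showed the largest rise, 7.02 ± 0.72 (130-fold, adjusted p = 0.0177), though only 2 siRNA samples measured it. Lcn2, the iron-carrier protein lipocalin-2 and a marker of reactive astrocytes, rose by 5.49 ± 0.66 (adjusted p = 0.0177), and the pentraxin Ptx3 by 4.67 ± 0.61 (adjusted p = 0.0128). The inflammation genes that rose were the neutrophil chemokine Cxcl2 by 5.42 ± 0.67 (adjusted p = 0.0262), the monocyte chemokine Ccl2 by 4.20 ± 0.62 (adjusted p = 0.0421) and Ptgs2, which encodes cyclooxygenase-2, by 3.58 ± 0.55 (adjusted p = 0.0177).

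Of the 39 called probes 6 were lower. Hpgd, which inactivates prostaglandins, fell by 5.38 ± 0.52 (41.6-fold, adjusted p = 0.00113), from a level of 4.34 ± 0.11 (SD, n = 5) in wild type to -1.06 ± 0.73 (SD, n = 4) in siRNA samples after realignment. The transferrin gene Trf (-3.48 ± 0.58), Nkain4 (-3.42 ± 0.57), Rin2 (-3.29 ± 0.57), the leukocyte actin regulator Coro1a (-2.97 ± 0.46; -0.91 and -0.66 at its other probes) and Tnfaip8l2 (-2.91 ± 0.48) fell as well, at adjusted p of 0.0247 to 0.0437. As deposited, array pairs as a random block left 0 calls, so none of the genes named above passed there. Without that block, Cxcl10, Tgtp1 and Hpgd passed with any single replicate left out, and each of the other called genes named above lost its call in at least 1 such fit. Steap4 lost it without wild-type replicate 3, 4, 5 or 6 (adjusted p 0.0529 to 0.0717) and had too few values in some other fits, Irf7 without siRNA replicate 3 or 4 (0.0716 and 0.0704), Ptx3 without either of these (0.0553), Lcn2 without siRNA replicate 1, 2 or 3 (0.0633 to 0.101) and Ccl2 without any 1 null or siRNA replicate (0.0548 to 0.219). Among the next genes by p, which did not pass, Ccdc39 had -2.58 (adjusted p = 0.0596; 0.0279 with the replicate block) and Nr4a3 -3.28 (adjusted p = 0.0609).

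In all, limma called 39 of 21584 probes between siRNA and wild type in the 14 samples as deposited, 33 higher and 6 lower, with a median change over all probes of -0.268 (log2). The balance turned under other settings: with array weights 550 were higher and 602 lower, and at an unadjusted p under 0.05 with at least 1.5-fold change 844 were higher and 1686 lower. Camera passed 10 of 37 lists. Of these, only that of fibroblasts and mural cells had enough complete probes for an estimated correlation, and it did not pass (adjusted p = 0.835 with an estimated correlation). Upward with called members went the interferon list (adjusted p = 3.64e-38; 28 members rose adjusted over the list alone), reactive astrocyte (1.42e-11; 11 rose adjusted over the list alone) and inflammation (9.6e-11; 7 rose adjusted over the list alone). With no called member each, the proteasome (median 0.70), Nrf2 (0.40), heat shock (0.37), translation factor (0.36) and ribosomal protein (0.28) lists passed upward and the oligodendrocyte (-0.80) and fibroblast and mural cell (-1.09) lists downward. Adjusted over the list alone, 3 Nrf2 genes rose and 1 oligodendrocyte gene fell. Without wild-type replicates 1, 2 and 5 the ribosomal protein median was -0.08 and the heat shock median -0.01, and with a batch term in addition the translation factor median was -0.05. Leaving out 1 replicate moved the ribosomal protein median to 1.45 to 1.76 (without wild-type replicate 3, 4 or 6) and the heat shock median to 0.07 to 1.07 (wild-type replicate 2 or 3). The medians of the proteasome ran from 0.38 to 0.96, of Nrf2 from 0.26 to 0.72, of translation factor from 0.26 to 0.60, of oligodendrocyte from -1.21 to -0.45 and of fibroblast and mural cell genes from -1.45 to -0.67. Without wild-type replicate 2 alone, the heat shock and translation factor lists had adjusted p = 0.0525 and 0.0845. The oligodendrocyte list did not pass without wild-type replicate 4 or null replicate 3 or 4 (adjusted p 0.0574 to 0.0721), nor the fibroblast and mural cell list without wild-type replicate 3 or 4, null replicate 3 or 4 or siRNA replicate 1 or 2 (0.0549 to 0.252). With the replicate block the oligodendrocyte, fibroblast and mural cell and translation factor lists had adjusted p = 0.0825, 0.0797 and 0.077. The microglia list, with 1 called member (3 fell adjusted over the list alone), had a median of -0.31 (adjusted p = 0.223). Leaving out siRNA replicate 1, 2, 3 or 4 left 13, 12, 8 or 10 calls, leaving out wild-type replicate 1, 3 or 4 left 21, 22 or 17, and leaving out null replicate 2 or 4 left 23 each. The replicate block over replicates 1 to 4 gave 315 calls (180 higher, 135 lower), and array pairs as a random block gave 0, with 2530 probes at an unadjusted p under 0.05 in the fit without it.

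In the realigned fit with a batch term, chosen after the columns had been seen, 1106 of 20330 probes were called (655 higher, 451 lower), and 147 (105 higher, 42 lower) with array pairs as a random block. Of the 39 probes called as deposited, 37 were tested there, 35 were called in the same direction, and 30 with array pairs; Tnfaip8l2, at -1.12 (adjusted p = 0.338), was not. Of 38 interferon genes 22 rose (32 adjusted over the list alone, median 2.19), 37 had positive changes, and 10 rose with array pairs. Cxcl10 rose by 5.98 ± 0.39 (adjusted p = 1.1e-05; 0.00013 with array pairs), Rsad2 by 4.29 ± 0.44 and the exonuclease gene Isg20 by 3.98 ± 0.39 (2.19 and 0.74 at its other probes, which did not pass). Of 24 inflammation genes 11 rose (15 adjusted over the list alone, median 1.66), and 5 with array pairs, among them the chemokines Ccl7 (5.72 ± 0.42) and Ccl5 (4.46 ± 0.46) and the cytokine Il6 (3.82 ± 0.40). Of 30 reactive astrocyte genes 9 rose and 1, the elastic fibre gene Fbln5, fell (median 0.91), and 6 and 1 with array pairs. Cxcl2 and Oasl1 were not tested, having too few values. Leaving out wild-type replicate 1, 3 or 4 left 613, 684 or 718 calls, and siRNA replicate 2, 3 or 4 left 554, 432 or 369.

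Of 23 measured microglia markers 8 fell in the siRNA samples in the realigned fit (15 adjusted over the list alone, median -1.56), and 2 with array pairs. The list had adjusted p = 0.634 with an estimated correlation. The lysosomal membrane gene Laptm5 fell by 2.62 ± 0.41 (adjusted p = 0.00326), Coro1a by 2.95 ± 0.45 (adjusted p = 0.00434) and Ly86, a partner of a Toll-like receptor homologue, by 3.75 ± 0.64 (adjusted p = 0.0055); Laptm5 and Ly86 also passed with array pairs. In the 14 samples as deposited, without a batch term, Laptm5 stood at -0.42 ± 1.20 and Ly86 at -3.28 ± 1.06, and neither passed. Nor did they in the realigned samples without a batch term (adjusted p = 0.212 and 0.0634), while both passed with a batch term in the 11 samples that were not moved (adjusted p = 0.000637 and 0.0124). The other Coro1a probe tested had 0.31. Ly86 averaged 4.80 ± 0.59 (SD, n = 5) in wild type, 3.73 ± 2.25 (SD, n = 4) in null and 1.13 ± 0.46 (SD, n = 4) in siRNA samples.

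Gsta3, a glutathione transferase, rose by 5.25 ± 0.40 (adjusted p = 4.8e-05) and by 4.82 ± 0.51 as deposited; the Nrf2 targets Nqo1 and Srxn1 rose by 2.98 ± 0.51 and 2.12 ± 0.32, and 4 of 28 Nrf2 genes rose and 1 fell (6 and 2 adjusted over the list alone). Array pairs left adjusted p = 0.119 for Nqo1 and 0.0584 for this Srxn1 probe, and no Nrf2 member called. Adk, adenosine kinase, fell by 5.28 ± 0.47 (adjusted p = 0.00888 with array pairs) and Aldoc, the astrocytic aldolase, by 3.41 ± 0.59 (adjusted p = 0.0456 with array pairs). The fibroblast genes Col3a1 and Dcn fell by 4.61 ± 0.90 and 4.48 ± 0.96, but not with array pairs (adjusted p = 0.206 and 0.152); Col3a1 also lost its call without wild-type replicate 3 or 4 (adjusted p = 0.0951 and 0.0542) and with the replicate block (0.0642), and Dcn without wild-type replicate 1 or siRNA replicate 2 (0.0531 and 0.0535). Of 22 fibroblast and mural cell genes 2 fell (5 adjusted over the list alone; median -0.71), of 40 G2/M genes 2 fell (2 adjusted over the list alone; median -0.62), and of 30 proteasome genes 1 rose (0 adjusted over the list alone; median 0.52). With array pairs 0 members of these 3 lists were called.

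These lists passed camera at a preset correlation (interferon 4.54e-28, inflammation 3.68e-13, microglia 5.55e-08, reactive astrocyte 1.42e-06, proteasome 0.00328, Nrf2 0.0144, G2/M 0.02, fibroblast and mural cell 0.0245, all adjusted). None held with an estimated correlation: the adjusted p was 0.187 for interferon, 0.181 for inflammation, 0.634 for microglia and for reactive astrocyte and 0.776 for the rest with an estimated correlation. Fry, which asks whether a list's genes move 1 way on balance, gave adjusted p = 0.00217 for interferon and for inflammation and 0.0283 for microglia and for reactive astrocyte, and passed no other list. It treated all samples as independent, although consecutive samples correlate, so these p-values may be too small. Within replicates 1 and 2 the siRNA minus wild-type median was 1.39 for interferon, 2.37 for inflammation, -1.85 for microglia, 0.39 for reactive astrocyte, -0.60 for fibroblast, 0.48 for Nrf2, 0.48 for proteasome and -1.38 for G2/M genes. Within replicates 3 and above these medians were 3.48, 2.06, -1.06, 0.90, -0.64, 0.01, 0.22 and 0.08, so the G2/M and Nrf2 shifts were not seen in both batches. The G2/M list did not pass without wild-type replicate 2 or 4 or siRNA replicate 1 or 2 (adjusted p 0.072 to 0.174), the Nrf2 list without wild-type replicate 3 or siRNA replicate 1 (0.0537 and 0.0839), nor the fibroblast list without replicate 3 or 4 of any group (0.111 to 0.207) or with the replicate block (0.0741).

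**Figure D3:**
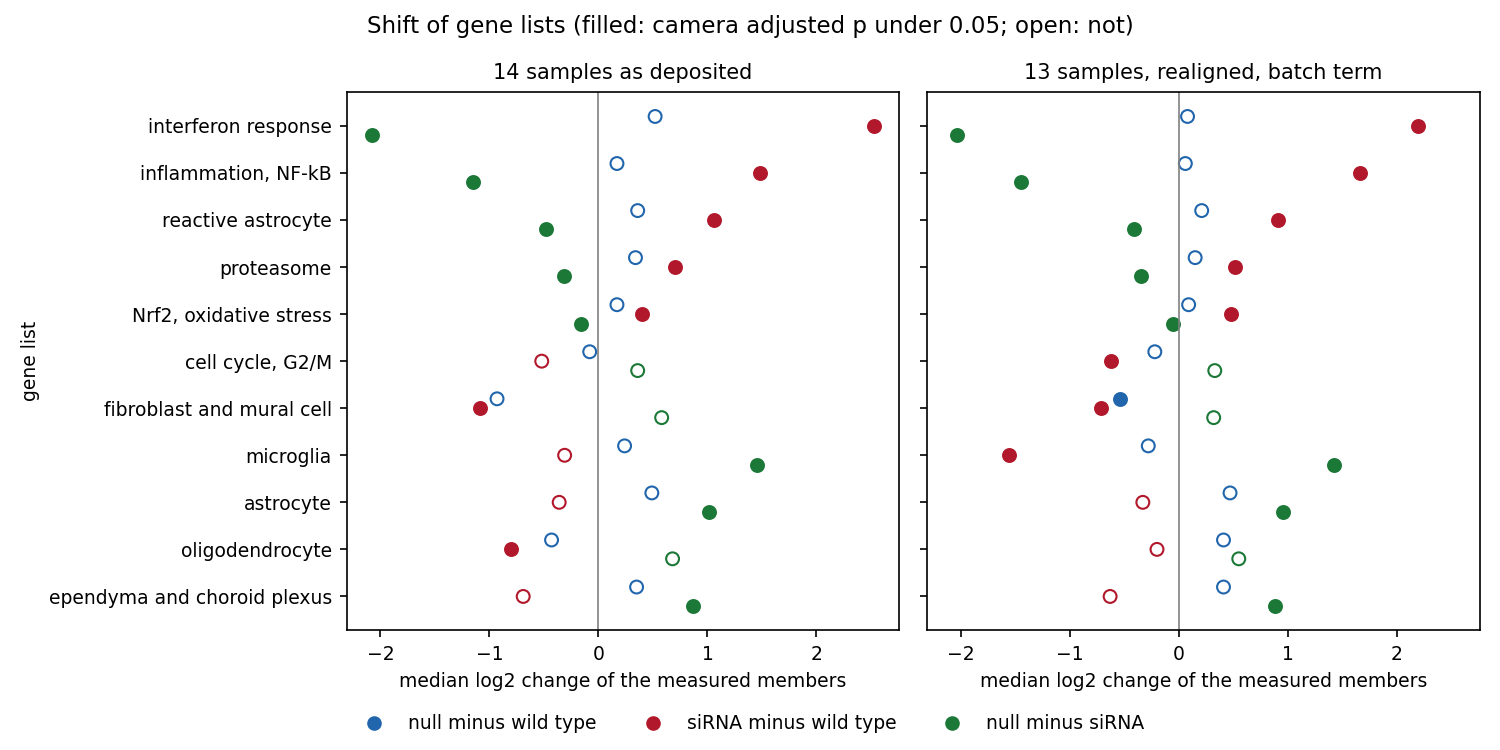
Median log2 change of the measured members of 11 gene lists in the 3 contrasts, in the 14 samples as deposited (left) and in the 13 realigned samples with a batch term (right). Filled points have a camera adjusted p under 0.05; the interferon list lies at 2.53 and 2.19 for siRNA minus wild type and at 0.08 for null minus wild type after realignment, and the microglia list moves from -0.31 to -1.56 for siRNA minus wild type.

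In the null samples limma called 0 of 21584 probes against wild type as deposited, with 1488 at an unadjusted p under 0.05. The probes with the smallest p did not pass (adjusted p 0.504 to 0.527); among them Bmpr1a, a BMP receptor, had a change of 2.44 ± 0.52, the ubiquitin ligase Itch 2.86 ± 0.60 and the spliceosome gene Snrnp70 -4.39 ± 0.65. Tmbim4, an inhibitor of apoptosis, and Il17f had 5.19 ± 0.66 and -4.47 ± 0.64 as deposited, but too few values to be tested after realignment. Their means were then 2.83 ± 0.47 (SD, n = 2) in wild type and 5.06 ± 0.13 (SD, n = 2) in null samples for Tmbim4, and -2.93 ± 0.60 (SD, n = 2) and -3.45 ± 0.50 (SD, n = 3) for Il17f. In the realigned fit with a batch term 25 probes passed (17 higher, 8 lower; adjusted p 0.0474 to 0.0493), and with array pairs 0 did, with 1590 at an unadjusted p under 0.05. Those 25 included Itch (3.18 ± 0.43), Bmpr1a (2.50 ± 0.40) and Tsc22d1 (2.80 ± 0.44) higher, and Snrnp70 (-4.35 ± 0.52), the cell cycle inhibitor Cdkn1a (-3.97 ± 0.48), Sgcb (-3.69 ± 0.50) and Gja1 lower. Other probes had changes of 0.25 for Bmpr1a, 0.79 and -0.97 for Tsc22d1 and 0.76 for Snrnp70, and did not pass. With the replicate block Bmpr1a, Tsc22d1, Snrnp70 and Sgcb did not pass (adjusted p 0.077 to 0.129), and each gene named here lost its call without wild-type replicate 1 (0.109 for Itch, Cdkn1a, Snrnp70 and Sgcb).

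The replicate block called 4 probes as deposited, all higher, and 3 after realignment. No list passed camera as deposited (smallest adjusted p = 0.0596). After realignment the fibroblast and mural cell list passed (22 measured, none called, median -0.54, adjusted p = 0.044; adjusted p = 0.999 with an estimated correlation), with within-batch medians of -0.65 and -0.46; without replicate 3 or 4 of any group it did not pass (adjusted p 0.115 to 0.351), nor with array pairs (0.06). The interferon list had a median of 0.08 (adjusted p = 0.989) and the microglia list of -0.28 (adjusted p = 0.321). Their batches opposed each other: the null minus wild-type medians were 0.32 and 0.37 in replicates 1 and 2. In replicates 3 and above they were -0.28 and -0.87, and the microglia median there was -1.06 for siRNA minus wild type. Of the realigned count, leaving out wild-type replicate 1 or 4, null replicate 2, 3 or 4, or siRNA replicate 1 or 4 left 0 calls, null replicate 1 or siRNA replicate 3 left 1, wild-type replicate 2 or 6 left 15 or 9, and wild-type replicate 3 or siRNA replicate 2 left 40 or 43.

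Genes of astrocyte coupling and signalling that were named in advance did not pass in either contrast as deposited. Panx1, which forms pannexin channels, had a change of 0.08 ± 0.49 in null and 1.75 ± 0.49 in siRNA samples (adjusted p = 0.204). In the realigned fit the siRNA value was 1.78 ± 0.41 (adjusted p = 0.0232; 0.21 with array pairs), and its other probe had 1.23; without wild-type replicate 1 or siRNA replicate 1 or 2 it did not pass (adjusted p 0.0588 to 0.0898). The junction scaffold gene Tjp1 had -0.58 in null and 0.40 in siRNA, and the purinergic receptor genes P2ry1, P2ry2 and P2ry4 had -0.60, 0.41 and -1.31 in null and -0.74, 1.09 and -1.01 in siRNA samples. The glutamate transporters Slc1a2 and Slc1a3 had 0.27 and 1.77 in null and 0.94 and 0.52 in siRNA, and the glutamine synthetase gene Glul 0.53 and -0.57. The water channel gene Aqp4 had -0.86 and -1.45 as deposited but 1.32 and 0.73 after realignment. The signs of Tjp1, P2ry4, and in 1 contrast each Panx1, P2ry2, Slc1a2 and Slc1a3, turned in some other fits. The connexin and pannexin list (5 measured) and the purinergic list (17 measured) did not pass, with medians of 0.91 and -0.27 in null and 0.27 and -0.14 in siRNA samples.

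Set directly against each other, null and siRNA samples differed in 19 probes as deposited, and in 0 with array pairs as a random block. Hpgd was higher in null by 4.61 ± 0.53 (24.4-fold, adjusted p = 0.00923) and the lectin gene Clec4a2 by 2.86 ± 0.43 (adjusted p = 0.0356; 0.0914 in the realigned fit with array pairs), while its other probes had -0.50 and -0.16. Lower in null were the chemokine Ccl7 (-6.06 ± 0.87), Tgtp1 (-5.60 ± 0.69), Gsta3 (-5.39 ± 0.52), the antiviral GTPase Mx2 (-5.33 ± 0.78) and Irf7 (-5.19 ± 0.84), at adjusted p of 0.00319 to 0.0455. Tcp11l2 (3.73), Rdm1 (3.14) and Pik3cg (3.16) came next among rises and did not pass (adjusted p 0.0574 to 0.0616), though Tcp11l2 and Rdm1 did with the replicate block (0.0469 and 0.0182), where Irf7 had 0.0519. Of 39 interferon genes 4 were lower in null (26 adjusted over the list alone; median -2.08), as were 3 of 27 inflammation genes (5 adjusted over the list alone; median -1.15) and 3 of 31 reactive astrocyte genes (9 adjusted over the list alone; median -0.48).

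In this contrast, which tests the difference between both manipulations, wild-type samples enter only through the shared spread and the dye and batch terms. It called 19 probes as deposited (3 higher and 16 lower in null; 4 with only the groups compared), 745 in the realigned fit (482 higher, 263 lower) and 64 with array pairs (18 higher, 46 lower). All 19 were called in the realigned fit and 17 with array pairs. Camera passed 8 lists as deposited: interferon (adjusted p = 1.51e-39), inflammation (9.91e-12), reactive astrocyte (1.13e-08), proteasome (median -0.32) and Nrf2 (-0.16) lower in null, and microglia (1.45, adjusted p = 2.18e-05; 2 rose adjusted over the list alone), ependyma and choroid plexus (0.87) and astrocyte (1.01, adjusted p = 0.0439) higher. Of these, the ependymal list had adjusted p = 0.632 with an estimated correlation, and the others could not be given one. The Nrf2 list did not pass with the replicate block (adjusted p = 0.0694). In the realigned fit 20 of 38 interferon genes were lower in null (9 with array pairs; adjusted p = 0.166 with an estimated correlation), 7 of 23 microglia genes were higher (none with array pairs; adjusted p = 0.7 with an estimated correlation) and 3 of 25 astrocyte genes were higher (none with array pairs; adjusted p = 0.7 with an estimated correlation). Camera passed 11 lists there, with immediate early (median -0.36), p53 (-0.28) and ribosomal protein (-0.09) genes lower in null in addition to those 8. None of the 11 passed with an estimated correlation (adjusted p 0.166 to 0.763 with an estimated correlation). Ribosomal proteins no longer passed with array pairs (adjusted p = 0.0797), and the p53 list no longer passed with the replicate block (0.214). The Nrf2 median of -0.05 there turned to 0.14 without null replicate 1 and to 0.11 with the replicate block, where the list passed downward all the same (adjusted p = 0.0428, mean change -0.43). The astrocyte, proteasome, Nrf2, p53 and ribosomal protein lists did not pass without null replicate 2, among others (adjusted p up to 0.349 over these fits).

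Within replicates 1 and 2 the null minus siRNA median was -1.27 for interferon, 2.10 for microglia, 1.05 for astrocyte and 1.02 for ependymal genes, and within replicates 3 and above -3.34, 0.29, 0.80 and 1.48. The Nrf2 median was -0.69 and then 0.47 and that of ribosomal proteins -0.21 and then 0.14, so their batches opposed each other, and that of immediate early genes was -0.51 and then -0.02. Inflammation (-0.90 and -1.65), reactive astrocyte (-0.66 and -0.76), proteasome (-0.76 and -0.18) and p53 genes (-0.20 and -0.11) kept their sign. Leaving out null replicate 1, 2, 3 or 4 left 2, 4, 4 or 3 calls as deposited, siRNA replicate 1, 2, 3 or 4 left 7, 4, 4 or 3, and wild-type replicate 3, 4 or 6 left 8, 11 or 11. Gsta3 passed in every one of these fits, and Hpgd in all but that without null replicate 1 (adjusted p = 0.0515). Tgtp1 lost its call without null replicate 1, 3 or 4 or siRNA replicate 3 or 4 (0.0502 to 0.0815), and Ccl7, Clec4a2, Mx2 and Irf7 without any 1 null or siRNA replicate (up to 0.178). The microglia list did not pass without null replicate 1 or 2 (0.0642 and 0.0844), the ependymal list without siRNA replicate 2 (0.063), and the astrocyte, proteasome and Nrf2 lists each without null replicate 2 or siRNA replicate 1 or 2, among others (up to 0.239). In the realigned fit, leaving out null replicate 1, 2, 3 or 4 left 332, 281, 328 or 189 calls and siRNA replicate 1, 2, 3 or 4 left 421, 360, 228 or 242. Array pairs as a random block in the 14 samples as deposited left 0, with 1375 probes at an unadjusted p under 0.05 in the fit without it.

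**Figure D4:**
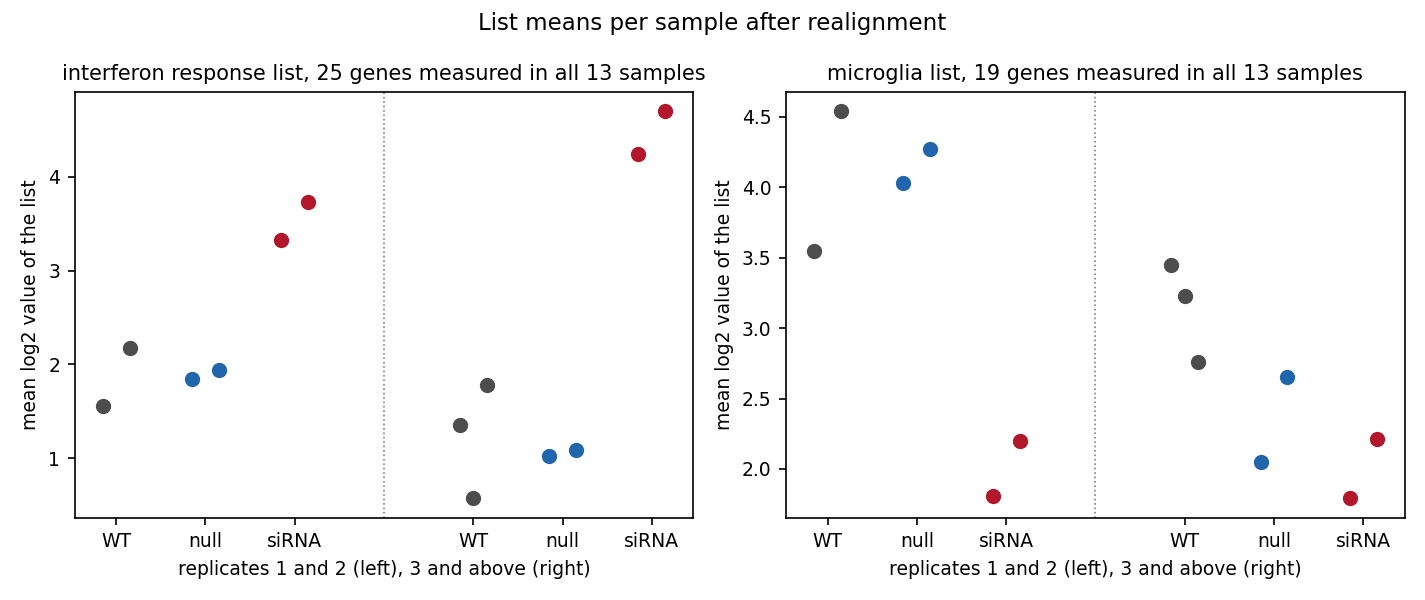
Mean log2 value of the interferon response genes (left) and microglia genes (right) measured in all 13 realigned samples, for each sample, by group and batch. All 4 siRNA samples lie above the wild-type samples of their batch for the interferon list, by a gap of at least 1.16, and below them for the microglia list, by a gap of at least 0.55.

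The null and siRNA changes against wild type were then compared over all probes. They correlated at r = 0.709 (jackknife SE 0.273) as deposited, with the same sign for 72.1% of probes. Both changes share the wild-type samples, and unchanged groups simulated against those controls gave r = 0.434 (0.408 to 0.455 over 20 simulations). The covariance was 1.05 against 0.356 simulated, a difference of 0.691. These simulated samples were independent; with array pairs correlated at 0.803, the consensus as deposited, the simulated r was 0.404 and the covariance 0.667, a difference of 0.38. No simulation held a difference between batches, or wild-type columns that stand apart from the rest as those described above do. Errors in such columns enter both changes, so the excess as deposited cannot be read as shared effects of both manipulations. With array weights r was 0.154 as deposited. When the wild-type samples were split between both changes, 18 values averaged r = 0.243 (-0.18 to 0.539). Splits that kept wild-type replicates 1 and 2 together gave -0.18 to 0.049, and splits that parted them gave 0.418 to 0.539. These columns correlate with each other at 0.975, so parting them did not give each change controls of its own. After realignment with a batch term r was 0.462 (jackknife SE 0.156), against 0.435 simulated with correlated array pairs, the covariance 0.353 against 0.21, and 4 values from splits averaged -0.01 (-0.167 to 0.177). Within replicates 1 and 2 r was 0.74, against 0.502 simulated (0.49 to 0.514), and the covariance 1.27 against 0.463. Within replicates 3 and above r was 0.313, against 0.378 (0.365 to 0.388), but the covariance 0.327 against 0.28.

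As deposited, the null contrast had no call to share with the siRNA contrast. In the realigned fit 10 probes were higher in both of 17 and 655, where independent lists would share 0.548, and 2 were lower in both of 8 and 451, where 0.177 would be shared. Unchanged groups simulated against the same controls, with correlated array pairs, had on average 43.8 null and 35.3 siRNA calls that were higher and shared 3.8 (0 to 13 over 20 simulations); of 40.2 and 34.6 lower calls they shared 3.85 (0 to 9). At an unadjusted p under 0.05, 910 probes were higher and 327 lower in both, against 268 and 110 for independent lists and 447 and 436 simulated. At both thresholds the simulated contrasts called other numbers of probes than the real ones. Shared counts depend on these numbers, so the simulated ones are no direct measure for the real overlap. The shared rises with a gene symbol were Bmpr1a, Tsc22d1, Ahcyl1, Nisch, Gpn2, Lman2, the zinc transporter Slc39a10 and Eif2s3y, and the shared fall was Acp1, a phosphatase (adjusted p = 0.0605 in null with the replicate block; -0.78 and -0.10 at its other probes). These names were chosen after their values were seen. Eif2s3y (1.94 ± 0.33 in null and 1.66 ± 0.33 in siRNA) lies on the Y chromosome, and the sex of the cultures is not given in the sources used here. Its other probe had 0.53 and 0.08 and did not pass. With array pairs none was shared. Part of any excess may come from the shared wild-type samples.

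A knockout allele carries flanking DNA of the strain in which it was made, so the genes next to Gja1 were examined in the null samples. Of the 50 genes on each side, 58 were measured, none was called (5 at an unadjusted p under 0.05), and the median change was 0.00 (limma's camera, adjusted p = 0.76 over 3 window sizes). Over all 21584 probes 0 were called and 1488 had an unadjusted p under 0.05, so no neighbour could have been called. The median and camera look for a shift in 1 direction, and changes in both directions would go unseen. After realignment the 57 measured neighbours had a median of 0.01 (adjusted p = 0.846), with none called and 8 at an unadjusted p under 0.05. Of all 20330 probes 25 were called and 3456 had an unadjusted p under 0.05 in that fit.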

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

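Of the tests in this part, the counts of other splits as deposited were set before the data were examined; the tests of the grid move, the interferon list and the microglia list, and all fits with the realigned columns, were chosen only after the result was seen. A sample was picked out where its gap to the nearest other sample of its group was large against the group's range. Among independent samples chance picks out about 1 in 20 groups. Consecutive samples correlate here and the genes examined were those named in the text, so that share may not apply. In these data 11 of 182 groups were picked, 6 of them among 167 groups of gene values.

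Wild-type replicate 5 was picked out on 3 measures: a highest value of 0.87 (7.22 to 8.66 in the other wild-type samples), an SD of 0.48 (2.35 to 2.78) and 726 distinct values (13675 to 17427). Null replicate 2 had 11766 distinct values against 14628 to 14910 in the other null samples. siRNA replicate 4 correlated with the mean of the other samples at 0.887, the other siRNA samples at 0.881 to 0.882. Among genes, Coro1a read 2.35 in null replicate 3 (3.49 to 3.66 in the others), Laptm5 4.91 in wild-type replicate 2 after realignment (3.30 to 3.62), Il6 1.60 in siRNA replicate 3 (1.29 to 1.30), Nqo1 -2.24 in null replicate 4 (-0.99 to -0.82), Aldh1l1 3.68 in null replicate 3 (1.98 to 2.25) and Ccdc39 -1.04 in siRNA replicate 3 (-2.36 to -2.16).

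Wild-type replicates 1 and 2 stood apart from the other samples as deposited. When each block column was moved to the grid row chosen on replicate 1 alone, replicate 2 correlated with the mean of wild-type replicates 3, 4 and 6 at 0.833, against 0.337 as deposited and 0.231 after the same search on a scrambled grid. Both columns correlate at 0.975 and may share an array, so replicate 2 is no independent column; the scrambled search kept that likeness and did not raise the correlation, which argues against weak or noisy hybridisation as the whole cause. It is consistent with values that stand against the wrong grid row in part of these columns. No biological explanation was tested.

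The interferon list was higher in the siRNA samples. A difference between the batches is argued against, because within each batch the lowest siRNA list mean lay above the highest wild-type mean, by at least 1.16. In each batch the siRNA samples are a pair that may share an array, so gaps between groups may include a difference between arrays. The microglia list's median of -1.56 shows no gain of microglia markers in the siRNA samples. Lower transcription of these markers would look like fewer cells, so the median cannot tell whether microglia contributed to the interferon response. Loss of the Gja1 transcript by itself is argued against by the null samples, whose Gja1 was lower still and whose list means lay at least 1.39 below every siRNA sample of their batch. The transfection or the small RNA itself, rather than its target, may have induced these genes, but it cannot be told apart from knockdown of Cx43, because the series has 0 mock-transfected samples. An effect that needs acute loss of Cx43 was not tested.

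The microglia list was lower in the siRNA samples after realignment. A batch difference is argued against by a gap of at least 0.55 between the lowest wild-type and the highest siRNA list mean of each batch. In each batch the siRNA samples are a pair that may share an array, so a difference between arrays would look alike. The astrocyte and the fibroblast and mural cell lists also lay below wild type in both batches, by gaps of at least 0.01 and 0.11. The oligodendrocyte list did not in replicates 1 and 2 (-0.42). Whether the wild-type columns alone make the pattern cannot be told apart from an effect of the siRNA: against the null samples the gap was 1.83 in replicates 1 and 2, with every null sample above every siRNA sample, but -0.16 in replicates 3 and above, where the groups overlapped. Of the measured members 91.3% were lower, which is consistent with fewer microglia in the siRNA cultures, but a lower transcription of these genes would look alike. Of the list's 32 genes, 3 stand in another list, and which of them astrocytes express is unknown.

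Other splits of the samples show how far chance can be excluded. As deposited, it could not be for siRNA against wild type, where 6 of 100 splits gave at least the 39 calls (highest other 4024) and 10 of 100 at least the 10 lists (13), nor for null against siRNA, where 2 of 35 gave at least the 19 calls (3489) and 4 of 35 at least the 8 lists (11). For null against wild type, with 0 calls and 0 lists, any split must give as many, so the count of splits says nothing about chance there. The highest other split gave 3399 calls and 11 lists. The split of null and siRNA samples along the batches gave the 3489 calls, against 19 for the real split in the same fit. In other fits the real split called 26 probes with the replicate block and 745 with a batch term after realignment. Splits that call several times the real count point to a structure of the samples. Splits that kept the array pairs together gave at most 73, 676 and 3489 calls in these contrasts.

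Within the batches of the realigned columns, 1 of 60 splits, the real one, gave the 1106 calls of siRNA against wild type (highest other 438). This excludes chance only where samples of a pair are independent, and they correlate (consensus correlation 0.539). Only 4 splits keep pairs together, the one with 438 calls among them, too few for a share under 0.05. Chance was not excluded for its 8 lists (13 of 60; highest other 12), nor for null against wild type, where 4 of 60 splits gave at least the 25 calls (1604) and 51 of 60 at least 1 list (8). For null against siRNA the 18 splits are too few for a share under 0.05; the real split gave 745 calls and 11 lists, 1 of 18 each, and the highest other 37 calls and 9 lists.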

How the results depend on the processing

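The tests with realigned columns or a batch term, within batches, or with 11 samples (without wild-type replicates 1, 2 and 5) were chosen only after the result was seen; the others were planned. Where a value moved, the cause was not tested unless given. In replicates 1 and 2 each group is a pair of consecutive samples, which correlated at 0.975 to 0.991 and may share an array. In replicates 3 and above the null and siRNA groups are such a pair too. The p-values and counts of these fits may therefore measure only the spread within an array, not between cultures. No intensity or background value was used, so the signal over background that limits these results is unknown.

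As deposited, the 0 calls of null against wild type became 4 with the replicate block, 1 with wild-type replicates 1 to 4, 6 with array weights, 25 realigned with a batch term, 104 with 11 samples and a batch term, 883 in replicates 3 and above, 6682 in replicates 1 and 2, and 1488 at an unadjusted p with at least 1.5-fold change; leaving out a replicate gave 0 to 1. The 39 calls of siRNA against wild type became 66 without the dye term, 0 with Cy3 or with Cy5 samples alone (fewer samples), 315 with the replicate block, 0 with array pairs, 23 with wild-type replicates 1 to 4, 9 with only the groups compared, 1 with probes measured in all samples (fewer genes), 1152 with array weights, 2530 at an unadjusted p, 7 at an adjusted p under 0.01, 67 with 11 samples, 162 realigned, 1106 with a batch term, 1465 with 11 samples and a batch term, 147 with array pairs added, 1795 in replicates 3 and above and 6890 in replicates 1 and 2, and leaving out a replicate gave 8 to 46. The 19 calls of null against siRNA became, in the same order from single dyes on, 0 and 0, 0 with array pairs, 12, 4, 3, 7797, 1375, 3, 75, 79, 745, 1665, 64, 1870 and 4997, and leaving out a replicate gave 2 to 27; the replicate block gave 26. Beyond these counts the replicate block changed the calls of genes and lists given beside the results, Acp1, Slc4a4 and Cdkn2b included, and no other call among those it was run for and described here.

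The lists passing as deposited moved from 0 for null against wild type to 7 with quantile normalization, 1 with the replicate block, 1 with wild-type replicates 1 to 4, 2 with 11 samples, 1 realigned, 1 with a batch term, 7 with 11 samples and a batch term, 4 in replicates 3 and above and 2 with the mean of a gene's probes (0 to 9 leaving out a replicate). For siRNA against wild type 10 became 5 with 11 samples and a batch term, 5 in replicates 3 and above and 0 with an estimated correlation or fry, which few lists had enough complete probes for (8 to 13), and for null against siRNA 8 became 5 in replicates 3 and above and 0 with either (4 to 11). The correlation of both changes, 0.709, was 0.154 with array weights and 0.299 in replicates 3 and above (0.55 to 0.817). Gja1 in null, -5.21 (-6.08 to -4.33), passed at -3.31 with a batch term, realigned or with 11 samples, and at -3.19 in replicates 3 and above; against siRNA, -2.90 (-3.68 to -2.12) passed at -2.90 with a batch term and -2.66 in replicates 3 and above. Gja1 in siRNA, -2.31 (-3.08 to -1.56 without single replicates), was -0.41 with a batch term, realigned or with 11 samples, -0.17 with array pairs added and -0.53 in replicates 3 and above, and passed in none.

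Realigned with a batch term, the 25 null calls became 115 with quantile normalization, 83 without the dye term, 13 with complete probes, 0 at an adjusted p under 0.01, 3 with the replicate block and 0 with array pairs (0 to 43 leaving out a replicate). The 1106 siRNA calls became 307 at an adjusted p under 0.01 and 147 with array pairs (369 to 1007), and the 745 calls of null against siRNA 160 and 64 (189 to 973). Gja1 in null lost its call at -3.07 with array pairs (-3.42 to -3.27), and against siRNA at -2.90 (-2.97 to -2.83). The null list became 0 with quantile normalization, 2 with complete probes, 3 with the replicate block and 0 with array pairs, an estimated correlation or fry (0 to 3); the 8 siRNA lists became 0 with an estimated correlation and 4 with fry (6 to 10), and the 11 of null against siRNA 0 and 4 (6 to 12). The correlation of 0.462 ran from 0.39 to 0.527.

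Direction turned past the threshold for genes in fits of replicates 1 and 2, where Aqp4 was 4.19 in null and 3.03 in siRNA, Tnfaip8l2 0.70 and Tjp1 -4.12 in siRNA, and with array weights, where P2ry1 was -1.07 for null minus siRNA. In replicates 1 and 2 that threshold rests on the spread within a pair of consecutive samples per group. Other genes turned too, each in a contrast where it passed neither as deposited nor in the realigned fit. In null against wild type, Panx1 (0.08) was -0.09 with Cy5 samples, -0.46 with array weights, -0.29 with 11 samples and -0.28 with a batch term added; Tjp1 (-0.58) was 1.38 with 11 samples and a batch term and 1.06 in replicates 3 and above. P2ry2 (0.41) was -0.85 with array weights and -0.12 with 11 samples, and P2ry4 (-1.31) 0.74 with either and 0.14 in replicates 3 and above. Slc1a2 (0.27) was -0.67 with either quantile normalization, -0.06 with Cy3 samples and -0.02 with array weights, and Aqp4 1.06 realigned, 1.32 with a batch term and 1.23 with array pairs added. In siRNA against wild type, Aqp4 was 0.48, 0.73 and 0.65 in these fits and Tjp1 (0.40) -0.60, -0.36 and -0.28, and -0.06 with 11 samples. P2ry4 (-1.01) was 1.04 with 11 samples, 0.18 with a batch term added and 0.10 realigned, and Slc1a3 (0.52) -0.25 with either quantile normalization and -0.56 in replicates 1 and 2. In null minus siRNA, P2ry1 (0.14) was -0.15 with Cy5 samples and -0.13 in replicates 1 and 2, and array weights gave P2ry4 (-0.30) 1.07 and Aqp4 (0.59) -0.36; P2ry4 was 0.25 in replicates 3 and above. Without single replicates as deposited, Panx1 in null ran from -0.24 to 0.36, Tjp1 from -1.58 to 0.26, P2ry2 from -0.03 to 0.84 and Slc1a2 from -0.15 to 0.67, Tjp1 in siRNA from -0.70 to 1.43, and in null minus siRNA Tjp1 from -2.04 to 0.05, P2ry1 from -0.30 to 0.51 and P2ry4 from -0.83 to 0.20. Realigned, Panx1 in null ran from -0.22 to 0.36, Aqp4 in siRNA from -0.06 to 1.28, Tjp1 from -1.09 to 0.63, P2ry4 from -0.21 to 0.08, and P2ry1 in null minus siRNA from -0.08 to 0.29. The median of the 20 genes on each side of Gja1 was -0.05 realigned, that of 50 being 0.01. In siRNA against wild type, the median of ribosomal proteins was -0.08 with 11 samples and -0.05 with a batch term added, of heat shock genes -0.01 with 11 samples, and of translation factors -0.05 with 11 samples and a batch term and -0.11 in replicates 3 and above. The Nrf2 median of null minus siRNA ran from -0.53 to 0.12 without single replicates, positive without null replicate 1 (0.12) or 2 (0.06), and was 0.44 in replicates 3 and above. Realigned, it ran from -0.32 to 0.14, positive without wild-type replicate 3 (0.02) or 6 (0.11) or null replicate 1 (0.14) or 2 (0.07), and was 0.11 with the replicate block, past the threshold (adjusted p = 0.0428) but downward by camera. The other values of single genes kept their direction, 1835 as deposited on the same side of the threshold, 282 weaker and 92 stronger, and 1463, 415 and 6 realigned; those of lists, 411 on the same side and 71 weaker as deposited, and 319 and 96 realigned.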

Other observations

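All values in this part come from the realigned fit with a batch term or from counts of measured probes, both chosen only after the result was seen. Immediate early genes, which respond within minutes to stimulation, rose in part in the siRNA samples: 5 of 31 rose (1 with array pairs; 6 rose and 2 fell adjusted over the list alone), with a median of 0.29 (camera, adjusted p = 0.244). Nr4a2, an orphan nuclear receptor, rose by 3.81 ± 0.41 (adjusted p = 0.000519; 0.00874 with array pairs), Fosl1, a subunit of AP-1, by 3.19 ± 0.58 (0.00694; 0.0845 with array pairs) and the transcriptional repressor Klf10 by 1.86 ± 0.35 (0.00855; 0.146 with array pairs). Of 21 genes of the p53 and cell cycle arrest list 2 rose (3 adjusted over the list alone, median 0.32). They were Plk2 by 1.72 ± 0.38 and the cell cycle inhibitor Cdkn2b by 1.33 ± 0.35. Neither passed with array pairs (adjusted p = 0.233 and 0.318), and Cdkn2b did not with the replicate block (0.0515).

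Gria2 and Gria1, subunits of AMPA receptors, had changes in the siRNA samples of -2.41 ± 0.43 (adjusted p = 0.00624; 0.0521 with array pairs) and -1.31 ± 0.32 (0.0325; 0.294 with array pairs). Of 25 astrocyte genes 1 rose and 2 fell (2 and 5 adjusted over the list alone, 0 and 1 with array pairs; median -0.33, camera adjusted p = 0.445): Aldh1l1, a folate enzyme and astrocyte marker, rose by 1.57 ± 0.42 (0.327 with array pairs), while Aldoc fell by 3.41 ± 0.59 and the bicarbonate transporter Slc4a4 by 1.65 ± 0.44 (0.0815 with the replicate block, 0.193 with array pairs). The growth factor binding protein gene Igfbp3 rose by 3.19 ± 0.44 (adjusted p = 0.0187 with array pairs), and the growth factor Ptn fell by 1.46 ± 0.31 (0.217 with array pairs). Plk2, Cdkn2b, Gria1, Aldh1l1, Slc4a4 and Ptn lost their calls without siRNA replicate 4, among others (adjusted p up to 0.179).

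Few probes were measured in every sample of some groups and in no sample of another. Across the samples used, 8 probes were measured in the siRNA group only (the named ones being Gstp3, H2-Q10, Slfn1 and Ifna6, which encodes an interferon alpha), 10 in the null group only and 3 in the wild-type group only, and 14 in null and wild-type but not in siRNA samples, among them Alox5 and Fli1. No gene of the interferon list was among them, though that list does not hold Ifna6 or Slfn1. Why a value is missing is not given in the sources used here.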
